A study of Mus musculus with 47 samples.

How the data were processed

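Poly(A) RNA of mouse gonadal fat pads was measured in 47 libraries of 3 strains, 2 sexes and 2 diets. Per the labels, RNA was extracted with MagMAX and TRIzol reagents, spiked with ERCC controls, made into libraries with the KAPA mRNA HyperPrep kit and sequenced in pairs on a NovaSeq instrument. The spike-ins were not used here. The submitters' notes name the GRCm38 build and DESeq2 without a role, and the aligner, the counting tool and the annotation release are not given in the sources used here.

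The deposited table of expected counts holds estimated counts per gene, of which 21.5% differed from a whole number by more than 1e-06, and these were rounded for the tests. The deposited log2 values are variance-stabilized by the authors and lay a median of 0.00564 from those of DESeq2 computed on the rounded counts. Deposited gene positions, in megabases, gave the chromosome, start and end printed here. GENCODE on GRCm38 gave the type of 22238 genes. Its positions overlapped the deposited ones for 99.98% of genes and had an equal start for 86.6%. There were 42 duplicated symbols, kept apart by gene ID.

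Library totals ran from 29.5 to 56.4 M counts, and the biological coefficient of variation was 0.192. Correlations of the deposited log2 values within a group were between 0.984 and 0.997. To look for a library deposited more than once, the chi-square per degree of freedom between libraries of a group was taken over genes with at least 20 counts in the pair, and it was between 12.6 and 192 (a repeat would be near 1). Mitochondrially encoded genes held 3.76% to 8.55% of the counts and the ribosomal gene Rn18s 0.918% to 3.27%. Each column was matched to its label, with 0 left over. The labels give sample numbers in 3 ID ranges, ORSAM77, ORSAM81 and ORSAM88, with 16, 16 and 15 libraries. As a term in the fit the range called 0 genes by edgeR, with 1070 at unadjusted p below 0.05, and no other tool was run on it. In NZO/HlLtJ the ranges follow diet by sex except within ORSAM77.

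Genes passing filterByExpr (minimum count 10) on the 12 groups were tested, 18769 of 22376 (83.9%). Counts were scaled by TMM and fitted in edgeR 4.0.16 (limma 3.58.1, R 4.3.3, data.table version 1.17.8) with 1 mean for each of the 12 groups of strain, sex and diet, which left 35 residual degrees of freedom. Contrasts were tested with the quasi-likelihood F test without the robust option, and genes with a Benjamini-Hochberg adjusted p below 0.05 were called. The contrasts were diet in each strain (mean of the female and male differences), diet in each strain and sex, the difference of diet effects between strains and between sexes, strain on 10% fat (sexes averaged) and sex on 10% fat. Any difference among the 3 strains was tested with 2 degrees of freedom. Test design, gene lists, panel, naming rule and most alternatives were fixed before the data were examined.

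The rule named, for diet in a strain, the 8 largest and 8 smallest log2 fold changes among called protein-coding genes with a mean log2 CPM of at least 1 and the same sign in both sexes, and the 5 largest and 5 smallest for other contrasts. It added a panel of 24 genes of fat biology, up to 3 called members of each list (at most 2 per direction), and check genes for sex and strain. Genes called in all 3 strains were ranked by the smallest of their 3 changes, after their values were seen. For each named call it was counted how many fits without a single library ended it.

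Lists covered adipocyte identity, de novo lipogenesis, cholesterol synthesis, fatty acid oxidation, oxidative phosphorylation (25 of 29 genes in the file), brown and beige fat (13 of 15), adipose expansion, macrophage, lipid-associated macrophage, inflammatory mediators, T and NK cell, B and plasma cell, neutrophil and mast cell, extracellular matrix, adipose progenitor, endothelial, mesothelial, unfolded protein response, interferon-stimulated, cell cycle, insulin signalling, antioxidant response, circadian clock, glucocorticoid response, immediate early, ovary with oviduct and uterus (7 of 13), mammary epithelium (4 of 9), skeletal muscle, erythrocyte and mitochondrially encoded genes. Lists of epididymis with testis (0 of 13 in the file) and pancreas acinar genes (0 tested) could not be tested. Camera with a preset correlation of 0.01 tested lists of at least 3 genes, and fry and an estimated correlation were the alternatives.

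Calling was tested on simulated counts, drawn for each gene from the means and dispersions fitted to the real data. Known folds were given to 200 genes. The draws hold no outlying libraries and no correlation between genes, so the rates below need not hold for the real counts. In C57BL/6J 59.7% of genes changed 1.5-fold, 68.7% changed 2-fold and 90.9% changed 4-fold were called, in NZO/HlLtJ 59.7%, 80.6% and 90.9%, and in NZO/HlLtJ males alone 53.7%, 68.7% and 81.8%. None was called in the wrong direction, and 3 of 149, 5 of 159 and 14 of 150 calls were false.

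Alternatives were DESeq2 size factors or library totals in the same fit, the DESeq2 1.42.0 Wald test, limma with a trend on the deposited log2 values, no filter (at least 1 count), a stricter filter (1 CPM in 12 libraries), the ID range as a term, only the strains compared, and leaving out each library in turn. After seeing the data 2 were added. The contrasts of NZO/HlLtJ were fitted within and outside ORSAM77, and all results without 7 doubted libraries, those with a list of another tissue or immune cell type over 2 log2 units above the median of the other libraries of the group. These are C57BL/6J female 10% fat replicates 1 (2.87) and 3 (5.36), CAST/EiJ male 44% fat replicate 2 (2.51), male 10% fat replicate 2 (2.30) and female 44% fat replicate 4 (3.00) for skeletal muscle, C57BL/6J male 10% fat replicate 3 (2.74) for mammary epithelium, and NZO/HlLtJ male 44% fat replicate 3 for B and plasma cell (3.19) and neutrophil and mast cell (2.23). No epididymis list could be scored, so the rule could not mark epididymal tissue. CAST/EiJ male 10% fat replicate 3, with high Rnase10 and Defb42, was therefore kept, while replicate 2 of the same group was left out. The fits without doubted libraries thus do not clear the CAST/EiJ results of tissue carried over. Random steps used seed 11.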

Results

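Gonadal fat pads of 3 inbred mouse strains were profiled by poly(A) RNA sequencing after a control or a high-fat diet. C57BL/6J is the common laboratory reference strain, CAST/EiJ is a wild-derived strain, and NZO/HlLtJ is a polygenic model of obesity in which males are prone to diabetes. Females and males of each strain ate a diet with 10% fat or a diet with 44% fat, each with fiber, from 6 weeks of age, and tissue was taken at 15 weeks. The 47 libraries formed 12 groups of 4, except for CAST/EiJ males on 10% fat with n = 3. The question put by the series title is how far the response to diet depends on the genotype.

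Deposited counts summed to between 29.5 and 56.4 M counts per library, with a median of 40.8 M. Totals ran from 29.5 to 43.2 M in C57BL/6J females on 10% fat and from 38.3 to 56.4 M in CAST/EiJ females on 10% fat. Of 22376 genes in the file, 18769 were tested, and 15514 of these were protein-coding. Xist (ENSMUSG00000086503), the RNA of the inactive X chromosome, was at 527 counts per M (CPM) or more in every female and at most at 1.84 in any male. Summed Y-linked genes reached at least 68.9 CPM in every male and at most 0.181 in any female, so the sex labels held for all libraries. Log2 fold changes are given with their standard error (SE), group means as CPM with the standard deviation (SD), and adjusted p values come from the edgeR quasi-likelihood test unless another tool is named. These p values measure the spread between libraries, since the labels do not state that each library came from a separate animal.

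Strain was the largest source of variance. Principal component 1 held 42.3% of the variance and set CAST/EiJ apart from the other strains, and component 2, with 17.9%, separated C57BL/6J from NZO/HlLtJ. NZO/HlLtJ females on 10% fat lay at one end of the NZO/HlLtJ groups on component 1, between -58.5 and -55.4, females on 44% fat between -81.1 and -77.2, males on 10% fat between -76.6 and -64.4 and males on 44% fat between -80.3 and -60.4. CAST/EiJ groups overlapped along component 1, from 93.3 to 109.

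**Figure D1:**
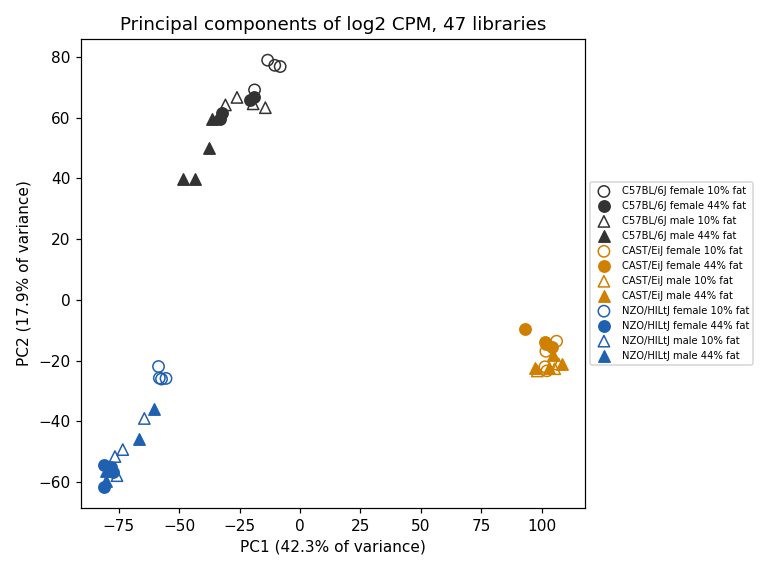
Principal components 1 (42.3% of the variance) and 2 (17.9%) of log2 CPM, with 1 symbol per library, colors for strain, circles for females, triangles for males and filled symbols for 44% fat. CAST/EiJ libraries lie between 93.3 and 109 on component 1, and those of the other strains below 0.

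In C57BL/6J the genes that rose most on 44% fat included Sfrp5, Mest, Mmp12 and Slc5a7. Sfrp5 (ENSMUSG00000018822, chromosome 19, 42197971 to 42202252, GRCm38), a secreted Wnt inhibitor of expanding fat, rose 7.57-fold (log2 2.92, SE 0.43, adjusted p = 1.71e-05, n = 16), from 2.30 ± 1.04 to 15.1 ± 14.6 CPM in females and from 14.2 ± 6.80 to 125 ± 81.2 in males. Mest (ENSMUSG00000051855, chromosome 6, 30723547 to 30748465, GRCm38), an imprinted gene linked to adipocyte enlargement, rose 6.61-fold (SE 0.42 log2, adjusted p = 4.42e-05). Slc2a5 (ENSMUSG00000028976, chromosome 4, 150119283 to 150144169, GRCm38), the fructose transporter GLUT5, fell 8.03-fold (log2 -3.01, SE 0.62, adjusted p = 0.000966). Across the strain 3145 genes changed, 1659 up and 1486 down, 463 of them by 2-fold or more.

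Rnase2a (ENSMUSG00000047222, chromosome 14, 51255266 to 51256112, GRCm38), an eosinophil-type ribonuclease, had the largest rise in C57BL/6J (log2 4.60, SE 0.67, adjusted p = 1.66e-05), yet only from 0.0401 to 0.941 CPM in females and from 0.166 to 4.63 in males. Slc5a7 (ENSMUSG00000023945, chromosome 17, 54273594 to 54299034, GRCm38), a choline transporter, rose 16.4-fold (SE 0.57 log2), from 1.84 ± 0.593 to 29.3 ± 19.3 CPM in males. Grid1 rose by log2 3.31 (SE 0.45) and Tph2, which encodes a tryptophan hydroxylase, by 3.33 (SE 0.69). Mmp12 (ENSMUSG00000049723, chromosome 9, 7344381 to 7369499, GRCm38), a macrophage metalloelastase, rose 6.92-fold (log2 2.79, SE 0.51, adjusted p = 0.000279) and reached 35.3 ± 29.7 CPM in males on 44% fat against 3.49 ± 3.02 on 10%. Serpina3k fell by log2 -2.09 (SE 0.45). Myh15, which was 0 in all females on 10% fat, was at 0.0811 CPM in females and 0.267 in males on 44% fat, and lost its call without the libraries described below (adjusted p = 0.105).

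Markers of fat mass moved with diet in C57BL/6J. Lep (ENSMUSG00000059201, chromosome 6, 29060220 to 29073877, GRCm38), which encodes leptin, rose 2.93-fold (log2 1.55, SE 0.35, adjusted p = 0.00219), from 391 ± 328 to 1101 ± 433 CPM in females and from 641 ± 242 to 1951 ± 857 in males. Npr3, a natriuretic peptide clearance receptor, rose by 1.13 (SE 0.29). Itgax, the CD11c integrin of adipose macrophages, rose 2.37-fold (SE 0.26 log2), to 20.7 ± 10.0 CPM in males, and Ccl2, a monocyte chemokine, rose 2.72-fold (SE 0.32 log2), from 2.98 ± 0.70 to 12.9 ± 6.24 CPM in males. Col6a3, a fibrosis-related collagen, rose by 0.75 (SE 0.19). Adipoq (adiponectin) was not called (log2 -0.19, SE 0.09, adjusted p = 0.116), nor were Fasn (-0.39, SE 0.26), Slc2a4 (-0.19, SE 0.14), Adgre1 (0.11, SE 0.14), Pparg (-0.04, SE 0.13), Scd1 (0.10, SE 0.15), Srebf1 (-0.09, SE 0.14), Sqle (0.58, SE 0.24), Irs1 (-0.28, SE 0.12), Insr (-0.07, SE 0.08), Adrb3 (-0.29, SE 0.19), Tnf (0.12, SE 0.32), Saa3 (0.65, SE 0.43), Col1a1 (0.25, SE 0.17) or Ucp1 (-1.27, SE 2.03). Acaca fell by log2 -0.78 (SE 0.24, adjusted p = 0.0207), but lost its call in 2 of 16 fits that left a library out.

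Several smooth-muscle, muscle and epithelial genes among the strongest falls in C57BL/6J rested on single libraries. Pcp4, at 0.559 ± 1.10 against 0.0145 ± 0.0289 CPM in males, had adjusted p = 0.758 without C57BL/6J male 10% fat replicate 3, and Actg2 (-2.30) and Cnn1 (-2.06), of smooth muscle, had 0.568 and 0.376. Elf5, an epithelial transcription factor, stood at 7.18 ± 14.3 CPM in males on 10% fat and at 0 on 44%, and had 0.449 without that library. Hoxa11, at 0 in males on 44% fat, lost its call in 7 of 16 fits, with an adjusted p of 1 without that library, and Elovl3 (-2.14), a brown-fat elongase, in 11. Slc27a2, a fatty acid transporter, had 0.285 without C57BL/6J male 10% fat replicate 2. The muscle gene Mylpf (-2.41, SE 0.61) had 0.0725 without C57BL/6J female 10% fat replicate 3, and 5 of 9 skeletal muscle genes fell (6 adjusted over the list alone), with a median of -1.95. Actn3 fell by -1.95, from 6.00 ± 7.09 to 0.721 ± 0.104 CPM in females. Leaving out 7 doubted libraries with high marker genes of another tissue or immune cell type, of which 3 were from C57BL/6J (female 10% fat replicates 1 and 3, male 10% fat replicate 3), was a choice made after seeing the data. It gave 1123 calls against 3145 from fewer samples, with Mylpf at -0.50. Npr3 was at 0.92 against 1.13 and Lep at 1.40 against 1.55, both no longer called.

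In C57BL/6J the called genes of the matrix and of sterol synthesis mostly rose, and mitochondrially encoded genes fell. In the extracellular matrix list 14 of 27 genes rose and 1 fell (17 and 1 adjusted over the list alone), with a median of 0.43, led by Col6a1 (0.86, SE 0.17), at 598 ± 91.8 against 888 ± 227 CPM in females, and Col18a1 (0.55, SE 0.11). Of 23 cholesterol genes 5 rose, among them Hmgcs1 (0.88, SE 0.15), and 7 adjusted over the list alone. Of 13 mitochondrially encoded genes 11 fell (11 adjusted over the list alone), among them mt-Co1 (-0.44, SE 0.09) and mt-Co3 (-0.48, SE 0.10). All 5 adipose expansion genes rose, 5 adjusted over the list alone. By camera with a preset correlation of 0.01 the expansion, mitochondrial, matrix and cholesterol lists had adjusted p = 9.56e-07, 2.44e-09, 2.86e-08 and 0.000199, against adjusted p = 0.245, 0.462, 0.686 and 0.788 with an estimated correlation.

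Immune and antioxidant genes moved less evenly in C57BL/6J. Of 14 lipid-associated macrophage genes 5 rose (7 and 1 down adjusted over the list alone), including Itgax and Mmp12, while Trem2 (0.86, SE 0.30) lost its call in 10 of 16 fits. Il1rn (1.68, SE 0.36) and Ccl2 were among 4 of 20 inflammatory genes that rose, 4 adjusted over the list alone, and Ighm, the IgM heavy chain, rose by 1.58 (SE 0.37). Sod3 (0.58, SE 0.09) rose and Gpx3 (-0.94, SE 0.21) fell, both extracellular antioxidant enzymes. Cfd, which encodes adipsin, fell by -0.96 (SE 0.23), from 4577 ± 614 to 1975 ± 1420 CPM in males. Cidea (-1.53, SE 0.43) and the female Ucp1 value, at 81.2 ± 64.9 against 15.8 ± 14.6 CPM, were lower on 44% fat, and the Ucp1 call in females ended in 4 of 8 fits. The lipid-associated macrophage and inflammatory lists had adjusted p = 0.788 and 0.686 with an estimated correlation.

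In CAST/EiJ the strongest change was the loss of Marc1 and of lipogenic genes on 44% fat. Marc1 (ENSMUSG00000026621, chromosome 1, 184786767 to 184811313, GRCm38), a mitochondrial amidoxime-reducing enzyme, fell 22.5-fold (log2 -4.49, SE 0.35, adjusted p = 1.85e-11, n = 15), from 121 ± 25.6 to 6.31 ± 2.70 CPM in females and from 32.8 ± 24.1 to 1.24 ± 0.55 in males. Elovl6 (ENSMUSG00000041220, chromosome 3, 129532355 to 129638495, GRCm38), a fatty acid elongase, fell 7.79-fold (SE 0.38 log2), from 708 ± 199 to 89.7 ± 35.0 CPM in females. Slc6a13 (ENSMUSG00000030108, chromosome 6, 121300227 to 121337733, GRCm38), a GABA and taurine transporter, rose 3.12-fold (log2 1.64, SE 0.20, adjusted p = 8.13e-07). In all 1709 genes changed, 676 up and 1033 down, 287 of them by 2-fold or more. The direction depended on the scaling, as 70.9% were higher under library totals against 39.6%, and 943 genes were called with the CAST/EiJ libraries alone.

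Lipogenesis fell broadly in CAST/EiJ. Fasn (ENSMUSG00000025153, chromosome 11, 120805846 to 120824547, GRCm38), the fatty acid synthase, fell 2.66-fold (log2 -1.41, SE 0.27, adjusted p = 0.000443), from 51840 ± 5980 to 18160 ± 5920 CPM in females and from 24250 ± 10800 to 9795 ± 2610 in males. Acaca (ENSMUSG00000020532, chromosome 11, 84129672 to 84401651, GRCm38) fell by -1.19 (SE 0.25) and the citrate carrier Slc25a1 by -1.38 (SE 0.19). Slc2a5 fell 10.3-fold. Of 20 lipogenesis genes 15 fell, 15 adjusted over the list alone (median -0.71, camera adjusted p = 2.24e-17), with adjusted p = 0.200 with an estimated correlation. Of 23 cholesterol genes 5 fell, including Fdft1 (-0.62, SE 0.14) and Tm7sf2 (-0.68, SE 0.16), and 17 fell and 1 rose adjusted over the list alone, with adjusted p = 0.665 with an estimated correlation. Without CAST/EiJ male 10% fat replicate 1 the Fdft1 call ended (adjusted p = 0.0603), as did that of Srebf1 (-0.59, SE 0.15), at 0.0732.

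Mest, Peg3, Zim1 and Nnat were among the rises in CAST/EiJ. Mest rose 6.15-fold (SE 0.45 log2, adjusted p = 0.000121), from 20.1 ± 7.05 to 80.4 ± 29.1 CPM in females and from 35.6 ± 22.4 to 336 ± 244 in males. Peg3 rose by 1.61 (SE 0.36), from 81.8 ± 45.1 to 284 ± 87.7 CPM in females, Zim1 by 1.84 (SE 0.39) and Nnat by 1.70 (SE 0.36). Irf4, a transcription factor of adipocytes and lymphocytes, rose by 2.16 (SE 0.53), with wide spread at 370 ± 433 CPM in males on 44% fat. Zbed6 (1.94, SE 0.62) lost its call in 9 of 15 fits. Sfrp5 was called in CAST/EiJ males (2.21, SE 0.62), from 21.3 ± 6.87 to 98.4 ± 31.4 CPM, but 6 of 7 fits without a library ended the call.

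Other falls in CAST/EiJ included single genes such as Sorcs2, Ppp1r3b and Slc2a4. Sorcs2, a sortilin-family receptor, fell by -2.69 (SE 0.31), from 158 ± 33.7 to 10.3 ± 6.34 CPM in females, Ttc25 by -3.31 (SE 0.39), Wisp2 by -3.03 (SE 0.43) and Tmem79 by -2.77 (SE 0.43). Ppp1r3b, a glycogen-targeting phosphatase subunit, fell by -2.10 (SE 0.36), and Slc2a4, the insulin-responsive transporter GLUT4, by -0.70 (SE 0.15). Irs2 rose 2.03-fold (SE 0.20 log2), and Irs1 rose by 0.45 (SE 0.13) with adjusted p = 0.0788 without CAST/EiJ male 10% fat replicate 1. Cpt1a (0.59, SE 0.08), of fatty acid oxidation, rose. Krt19 (1.05, SE 0.22) and Msln (0.91, SE 0.24) were among 5 of 11 mesothelial genes that rose, 9 adjusted over the list alone, with adjusted p = 0.555 with an estimated correlation. Lep (log2 -0.00, SE 0.36), Adipoq (0.12, SE 0.09) and Itgax (-0.31, SE 0.29) were not called in CAST/EiJ, nor were Pparg, Scd1, Sqle, Npr3, Ucp1, Insr, Adrb3, Adgre1, Trem2, Ccl2, Tnf, Col1a1, Col6a3, Saa3 or, over both sexes, Sfrp5 (1.09, SE 0.42).

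In NZO/HlLtJ adiponectin, the beta-3 adrenergic receptor and Cyp2e1 fell on 44% fat, mostly through females. Adipoq (ENSMUSG00000022878, chromosome 16, 23146536 to 23158028, GRCm38), a hormone of healthy adipocytes, fell 1.65-fold (log2 -0.72, SE 0.09, adjusted p = 1.78e-06, n = 16), from 2318 ± 63.9 to 915 ± 128 CPM in females against 1301 ± 115 and 1215 ± 321 in males. Adrb3 (ENSMUSG00000031489, chromosome 8, 27225776 to 27229588, GRCm38) fell by -0.97 (SE 0.19), from 203 ± 48.0 to 51.5 ± 16.4 CPM in females. Cyp2e1 (ENSMUSG00000025479, chromosome 7, 140763739 to 140774975, GRCm38), a microsomal cytochrome P450, fell 10.2-fold (log2 -3.35, SE 0.35, adjusted p = 1.14e-07), from 674 ± 245 to 23.9 ± 15.5 CPM in females and from 55.2 ± 43.5 to 15.1 ± 8.51 in males. In all 2364 genes changed, 1084 up and 1280 down, 242 of them by 2-fold or more, while under library totals 61.0% were higher against 45.9%.

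The NZO/HlLtJ samples carry a limit in their sample numbers. All 4 groups had 2 libraries in the ID range ORSAM77, but the other libraries of females on 10% and of males on 44% fat came from ORSAM81 and those of the other groups from ORSAM88, so diet by sex aligns with the ID range there. After seeing this the contrasts were fitted within ORSAM77 and outside it, with 8 libraries each. Female Adipoq was -1.30 within and -1.37 outside, Adrb3 -1.76 and -2.27, and Ccl2 2.54 and 2.33. Called genes for diet in NZO/HlLtJ numbered 19 within and 68 outside, and the Pearson correlation of the diet effects across genes was 0.283.

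Lipogenic genes fell in NZO/HlLtJ over both sexes. Thrsp (ENSMUSG00000035686, chromosome 7, 97412938 to 97417730, GRCm38), a lipogenic regulator, fell 3.63-fold (log2 -1.86, SE 0.32, adjusted p = 0.000187), from 590 ± 299 to 171 ± 69.4 CPM in females and from 335 ± 323 to 87.3 ± 14.7 in males. Slc2a5 fell by -3.46 (SE 0.60), Elovl6 by -1.73 (SE 0.36), Fasn by -1.10 (SE 0.26) and Acaca by -1.17 (SE 0.24). Of 20 lipogenesis genes 8 fell, 8 adjusted over the list alone, with adjusted p = 0.365 with an estimated correlation. Slc2a4 fell by -0.69 (SE 0.14) and Irs1 (ENSMUSG00000055980, chromosome 1, 82233101 to 82291416, GRCm38), the insulin receptor substrate, by -0.58 (SE 0.12). Srebf1 (-0.43, SE 0.14) lost its call in 11 of 16 fits. Tmem79 (-1.85, SE 0.39), Prrt4 (-1.87, SE 0.33) and Slc25a48 (-1.71, SE 0.37) also fell, and Rhbg, an ammonium transporter at 0.654 ± 0.26 against 0.221 ± 0.152 CPM in females, lost its call in 9 of 16 fits. Lep (0.22, SE 0.34), Mest (0.06, SE 0.40) and Sfrp5 (-0.44, SE 0.37) were not called in NZO/HlLtJ, nor were Pparg, Npr3, Ucp1, Scd1, Sqle, Insr, Trem2, Ccl2, Tnf, Col1a1, Col6a3 or Saa3.

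Adipocyte genes fell and macrophage genes rose in NZO/HlLtJ over both sexes, with list medians of -0.65 and 1.01 in females and 0.03 and -0.06 in males. Of 20 adipocyte identity genes 11 fell (12 adjusted over the list alone), including Cfd (-1.24, SE 0.23), at 1333 ± 118 against 357 ± 105 CPM in females, and adjusted p = 0.136 with an estimated correlation. In the macrophage list 12 of 18 rose and 1 fell (13 and 2 adjusted over the list alone), among them the scavenger receptor Msr1 (0.85, SE 0.16), while Cd163, a marker of resident macrophages, fell by -0.76 (SE 0.16). Of 14 lipid-associated macrophage genes 9 rose (12 adjusted over the list alone). With an estimated correlation these lists had adjusted p = 0.188 and 0.136. Adgre1 (0.66, SE 0.14) and Itgax (0.83, SE 0.23) rose, as did Olr1, an oxidized lipoprotein receptor, by 1.56 (SE 0.33), from 1.68 ± 0.217 to 11.7 ± 4.33 CPM in females. Cntn1 (1.75, SE 0.34), Fbln7 (1.39, SE 0.23), Pcp4l1 (1.38, SE 0.24) and Zim1 (1.44, SE 0.37) were also among the largest rises.

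Some neutrophil genes called in NZO/HlLtJ rested on a single sample. Ngp (4.23, SE 0.84) and S100a9 (3.35, SE 0.64) stood at 24.4 ± 48.1 and 24.1 ± 46.7 CPM in males on 44% fat, and had adjusted p = 0.185 and 0.135 without NZO/HlLtJ male 44% fat replicate 3. Without the same library Itgad (1.42, SE 0.38) had 0.0517. That library also carried B cell genes 3.19 log2 units above the median of its group, and Saa3 at 32.8 CPM. In the neutrophil and mast cell list 5 of 13 rose, 7 adjusted over the list alone, with adjusted p = 0.365 with an estimated correlation, and in females, which that library does not enter, 2 rose (median 0.48).

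Mesothelial, respiratory and cell cycle genes changed in NZO/HlLtJ as well. Muc16 (ENSMUSG00000109564, chromosome 9, 18495455 to 18674530, GRCm38), a mesothelial mucin, fell by -1.36 (SE 0.23), from 23.7 ± 4.78 to 5.14 ± 2.05 CPM in females, as 1 of 6 of 11 mesothelial genes that fell, 10 adjusted over the list alone, with adjusted p = 0.136 with an estimated correlation. Of 25 oxidative phosphorylation genes 15 fell (23 adjusted over the list alone, median -0.27), with adjusted p = 0.365 with an estimated correlation. Cdk1 (0.62, SE 0.18), the mitotic kinase, was among 6 of 18 cell cycle genes that rose, 15 adjusted over the list alone, with adjusted p = 0.365 with an estimated correlation, and it had 0.055 without NZO/HlLtJ male 10% fat replicate 2. Leaving out NZO/HlLtJ male 10% fat replicate 2 also lowered the count from 2364 to 1542 genes.

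**Figure D2:**
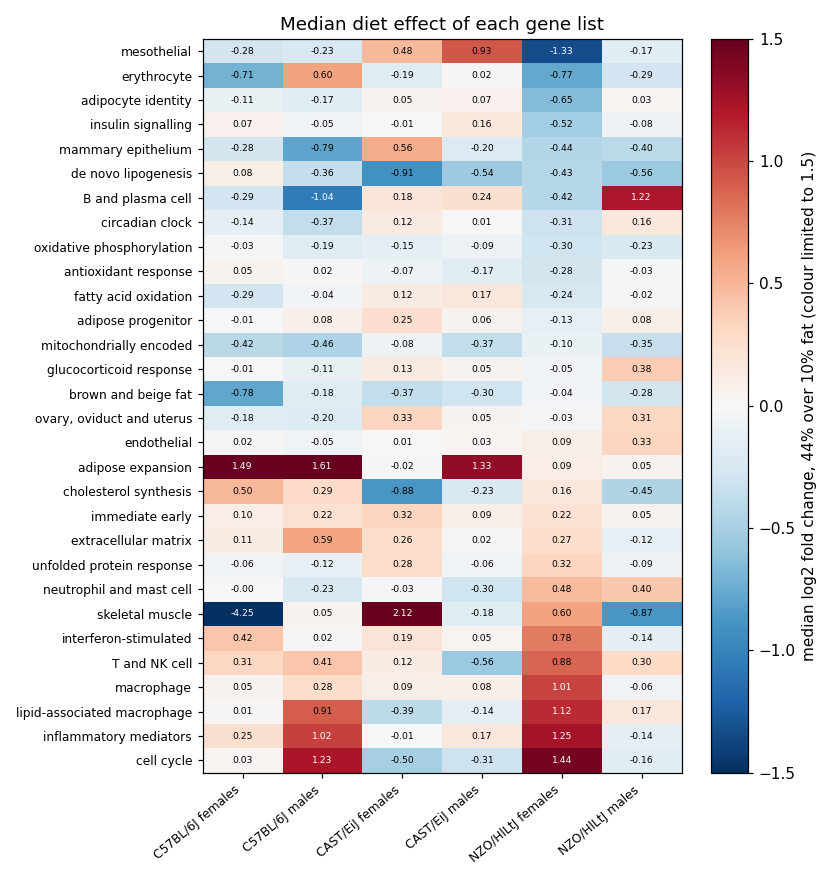
Median log2 fold change, 44% against 10% fat, of each gene list (lines) in each strain and sex (columns), printed in the cells, with colors limited to 1.5 log2 units in each direction. Cell cycle genes stand at 1.44 and mesothelial genes at -1.33 in NZO/HlLtJ females.

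The response to diet differed between strains for named markers. Averaged over the sexes, Adipoq fell by 0.84 log2 units more in NZO/HlLtJ than in CAST/EiJ (SE 0.12, adjusted p = 3.32e-05, n = 31) and by 0.53 more than in C57BL/6J (SE 0.12, adjusted p = 0.00547, n = 32). The NZO/HlLtJ effect was -1.34 in females and -0.10 in males. In C57BL/6J males Adipoq ran from 2971 to 3372 CPM on 10% fat and from 2303 to 2678 on 44%, so the larger fall in NZO/HlLtJ does not hold for males. Strains were not compared within a sex by a test. Mest rose by 2.67 log2 units less in NZO/HlLtJ than in C57BL/6J (SE 0.57) and by 2.56 less than in CAST/EiJ (SE 0.59), where NZO/HlLtJ stood at 312 ± 113 CPM in females already on 10% fat, against 28.8 ± 23.3 in C57BL/6J and 20.1 ± 7.05 in CAST/EiJ. Marc1 differed by -5.24 (SE 0.45, adjusted p = 4.68e-10) between CAST/EiJ and C57BL/6J, with C57BL/6J females at 50.5 ± 35.4 and 75.4 ± 14.3 CPM on 10% and 44% fat. The diet effect differed in 1726 genes between NZO/HlLtJ and C57BL/6J, in 1549 between CAST/EiJ and C57BL/6J, in 1551 between NZO/HlLtJ and CAST/EiJ, and in 3335 among any of the 3 strains.

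Between NZO/HlLtJ and C57BL/6J the largest differences were in Rnase2a (-5.83, SE 0.74), Slc5a7 (-3.37, SE 0.71), Sfrp5 (-3.36, SE 0.56, adjusted p = 0.000264) and Grid1 (-3.20, SE 0.58). Slc5a7 stood at 32.5 ± 9.96 and 75.4 ± 36.8 CPM in NZO/HlLtJ females, above any C57BL/6J group, and Sfrp5 at 88.8 ± 46.4 and 27.8 ± 5.74. In the other direction Acot1, an acyl-CoA thioesterase, differed by 2.15 (SE 0.43), Pcp4l1 by 2.12 (SE 0.33) and Cntn1 by 2.07 (SE 0.51). Ctnna2, near 0 in C57BL/6J, lost its call in 13 of 32 fits and Elovl3 (2.94) in 6, and S100a9 (3.92) had adjusted p = 0.113 without NZO/HlLtJ male 44% fat replicate 3. Without the 7 doubted libraries the count was 841 against 1726.

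Between CAST/EiJ and C57BL/6J, Mmp12 (-4.10, SE 0.82), Rnase2a (-4.27, SE 0.77) and the unannotated D430019H16Rik (-3.25, SE 0.56) differed downward and Irf4 upward (3.33, SE 0.72, adjusted p = 0.00478). Irf4 stood at 86.5 ± 71.1 and 27.8 ± 20.3 CPM in C57BL/6J females on 10% and 44% fat. Irs1 differed by 0.74 (SE 0.18), Itgax by -1.55 (SE 0.38) and Sqle, squalene epoxidase, by -1.31 (SE 0.35), the last with adjusted p = 0.0746 without CAST/EiJ male 10% fat replicate 1. Lep (-1.55, SE 0.49) and Sfrp5 (-1.83, SE 0.59) lost their calls in 17 and 21 of 31 fits, and Fabp3 (3.06) and Neb (2.19) in 11 each. Cnn1 (2.42) had 0.194 without C57BL/6J male 10% fat replicate 3, Stra6l, at most at 0.105 CPM in CAST/EiJ groups, had 0.134 without CAST/EiJ male 10% fat replicate 1, and Ptn (2.05) had 0.197 without the doubted libraries, which lowered the count from 1549 to 715 and left Itgax at 0.0540. Of 23 cholesterol genes 11 differed downward (21 adjusted over the list alone), with adjusted p = 0.475 with an estimated correlation. Without CAST/EiJ male 10% fat replicate 1 the count was 899.

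Between NZO/HlLtJ and CAST/EiJ, Marc1 differed by 4.43 (SE 0.44, adjusted p = 2.36e-08), with NZO/HlLtJ females at 80.7 ± 13.6 and 84.6 ± 19.8 CPM. Cyp2e1 differed by -3.37 (SE 0.47, adjusted p = 1.50e-05), with CAST/EiJ females at 3941 ± 865 and 5657 ± 645 CPM against 674 ± 245 and 23.9 ± 15.5 in NZO/HlLtJ. Wisp2 (3.88, SE 0.56), Olr1 (3.60, SE 0.74) and Chst4 (-2.63, SE 0.48), a sulfotransferase, also differed, as did Irs1 (-1.03, SE 0.18) and Adrb3 (-1.17, SE 0.27). Irf4 (-2.45) lost its call in 3 of 31 fits, Itgax (1.14) in 17, and Rhbg had adjusted p = 0.0738 without NZO/HlLtJ male 10% fat replicate 2. Ngp (4.55) and S100a9 (3.69) had 0.263 and 0.172 without NZO/HlLtJ male 44% fat replicate 3. Of 11 mesothelial genes 9 differed downward (10 adjusted over the list alone), with adjusted p = 0.0532 with an estimated correlation, and 10 of 14 lipid-associated macrophage genes upward (12 adjusted over the list alone), with 0.102.

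Some changes were shared by the strains. Slc2a5 fell in all 3, as did Elovl6 (-1.09 in C57BL/6J, -2.96 in CAST/EiJ, -1.73 in NZO/HlLtJ), Sorcs2 (-1.21, -2.69, -1.26) and Acaca (-0.78, -1.19, -1.17). AA467197, the mouse counterpart of C15orf48, rose in all 3 (0.88, 0.77, 1.06). Of 98 genes called in all 3 strains, 55 fell in each, 12 rose in each and 31 moved in mixed directions, and no number expected by chance was computed for the 3 together. Over all tested genes the diet effects of NZO/HlLtJ and C57BL/6J had a Pearson correlation across genes, which are not independent replicates, of 0.077 (jackknife SE 0.069), those of CAST/EiJ and C57BL/6J 0.111 (SE 0.090), and those of NZO/HlLtJ and CAST/EiJ 0.0015 (SE 0.065). The female and male effects correlated at 0.259 in C57BL/6J, 0.127 in CAST/EiJ and 0.058 in NZO/HlLtJ. The NZO/HlLtJ effects within and outside ORSAM77 correlated at 0.283. Genes that fell in both NZO/HlLtJ and C57BL/6J numbered 241 where 101 were expected from the list sizes and those that rose in both 137 (95.8 expected), against 29 (85.8) and 70 (113) in opposite directions. For CAST/EiJ and C57BL/6J 165 fell in both (81.8) and 167 rose in both (59.8), against 22 (53.5) and 43 (91.3) in opposite directions. For NZO/HlLtJ and CAST/EiJ 170 fell in both (70.4) and 47 rose in both (39.0), but 71 fell in NZO/HlLtJ and rose in CAST/EiJ (46.1) and 40 moved the other way (59.7).

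The diet effects measured in NZO/HlLtJ females and males differed, in a design where the ID range aligns with diet by sex. Ccl2 (ENSMUSG00000035385, chromosome 11, 82035571 to 82037453, GRCm38) differed by -3.42 log2 units between the male and the female effect (SE 0.56, adjusted p = 0.000302, n = 16), from 5.50 ± 1.58 to 29.8 ± 4.75 CPM in females and from 30.4 ± 10.7 to 15.4 ± 12.6 in males, where 44% fat replicates 1 and 4 stood at 3.3 and 5.8 CPM and replicates 2 and 3 at 24.6 and 27.8. Adipoq differed by 1.24 (SE 0.17, adjusted p = 4.24e-05), falling in females by -1.34 (SE 0.12) with no call in males (-0.10, SE 0.12). Adrb3 differed by 2.03 (SE 0.38, adjusted p = 0.00101), and fell in females by -1.98 (SE 0.28). In NZO/HlLtJ 3960 genes changed in females, 1044 of them by 2-fold or more, and 218 in males, and 2287 genes differed between the sexes in their response.

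Some inflammatory genes were among the largest downward differences between the sexes in NZO/HlLtJ, while 1178 of 2287 genes differed upward. Ptx3, a pentraxin, differed by -3.96 (SE 0.62), from 4.49 ± 1.25 to 31.3 ± 7.22 CPM in females, the chemokine Ccl7 by -3.33 (SE 0.59), the AP-1 member Fosl1 by -2.84 (SE 0.43) and the growth factor Ptn by -3.53 (SE 0.80). Msr1 differed by -1.80 (SE 0.31) and Adgre1 by -1.08 (SE 0.29). Peg3 differed upward by 3.37 (SE 0.68), at 69.6 ± 27.0 against 336 ± 250 CPM in males, Inmt by 4.53 (SE 0.99) and Rdh16 by 4.20 (SE 0.97), while Ripk4 (3.96) lost its call in 8 of 16 fits. Irs1 (0.84) and Scd1 (1.09) lost theirs in 3 of 16 fits, and Insr (0.50) and Sfrp5 (2.47) in 5. Trem2 rose in females by 1.23 (SE 0.38), from 37.0 ± 4.32 to 86.7 ± 11.3 CPM, without a called difference between the sexes (-1.16, adjusted p = 0.139).

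Genes of several lists differed between the sexes of NZO/HlLtJ in their diet effect, while with an estimated correlation no list of these 4 was called for the difference. In females 14 of 20 adipocyte identity genes fell (16 adjusted over the list alone, median -0.65), with adjusted p = 0.0393 with an estimated correlation, and the male and female effects differed in 10 (13 adjusted over the list alone), with 0.115. All 18 cell cycle genes rose in females, 18 adjusted over the list alone, with 0.166, and 15 differed by sex, all lower in the male effect (18 adjusted over the list alone), with 0.227. In the macrophage list 15 of 18 rose in females and 1 fell (15 and 1 adjusted over the list alone), with 0.0727, and 13 differed by sex (15 down and 1 up adjusted over the list alone), with 0.121. Of 11 mesothelial genes 10 fell in females, 10 adjusted over the list alone, with 0.0727, and 4 differed by sex (6 adjusted over the list alone).

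In these NZO/HlLtJ samples the ID range limits the sex difference. Within ORSAM77 no gene was called for diet by sex by edgeR (2320 at unadjusted p below 0.05), outside it 75 were called, and the correlation of the effects across genes was 0.237 (Pearson) and 0.475 (Spearman). Ccl2 differed by -3.45 within and -3.34 outside, and Adipoq by 1.21 and 1.29. The panel genes Pparg (0.48 and -0.14), Mest (0.33 and -0.60), Srebf1 (0.25 and -0.23) and Npr3 (-0.06 and 0.04) differed in sign. Leaving out NZO/HlLtJ male 44% fat replicate 1 gave 1067 calls, male 44% fat replicate 4 gave 1402 and male 10% fat replicate 4 gave 1225, against 2287. No panel gene was called in NZO/HlLtJ males, where counts ran from 15 without male 44% fat replicate 4 to 859 without male 44% fat replicate 3, and male 10% fat replicates 1, 2 and 4 and male 44% fat replicates 1 and 2 gave 57, 66, 36, 16 and 353.

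In CAST/EiJ 53 genes differed by sex in their diet response, none of the 10 largest in every fit that left a library out. Amph, an endocytic adaptor, differed by 1.72 (SE 0.33), from 11.7 ± 2.03 to 3.16 ± 0.857 CPM in females and from 20.1 ± 1.68 to 17.8 ± 1.02 in males, and lost its call in 3 of 15 fits, with adjusted p = 0.0817 without CAST/EiJ male 10% fat replicate 3. Foxred2 (1.91, SE 0.41), Mgat3 (1.91, SE 0.43), Gnao1 (1.43, SE 0.31) and Slc39a6 (1.16, SE 0.26) had 0.143, 0.143, 0.18 and 0.143 without that library. Teddm2 (-7.96), at 180 ± 311 CPM in males on 10% fat, 9230104L09Rik (-7.60), Egr2 (-4.16), Hs3st3b1 (-3.92) and St8sia6 (-3.14) owed their values to the same library, without which Teddm2 had 0.954. The count was 4 without CAST/EiJ male 10% fat replicate 3, 362 without replicate 1 and 104 without replicate 2 of that group, and 11, 11, 35, 11, 14 and 8 without female 44% replicates 1 and 2, female 10% replicates 2 and 4 and male 44% replicates 2 and 4. In C57BL/6J edgeR called 0 genes for diet by sex, with 1216 at unadjusted p below 0.05, DESeq2 called 58 and limma 12. Without C57BL/6J female 10% fat replicates 2 and 4, female 44% replicates 1 and 4, male 44% replicate 3 or male 10% replicate 1 edgeR called 41, 3, 2, 2, 14 or 5.

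The effect of diet within each sex was counted as well, with 1368 in C57BL/6J females, 711 in C57BL/6J males, 1232 in CAST/EiJ females and 388 in CAST/EiJ males. With only the libraries of the strain fitted, these counts were 1171, 277, 623 and 23. In C57BL/6J females Mest rose by 3.21 (SE 0.61) and Sfrp5 by 2.71 (SE 0.63), while in males Sfrp5 rose by 3.13 (SE 0.58), Ccl2 by 2.11 (SE 0.42), Itgax by 1.56 (SE 0.34), Col6a3 by 0.94 (SE 0.26) and Mest by 2.24 (SE 0.59), and Acaca fell by -1.24 (SE 0.34). In CAST/EiJ females Mest rose by 2.00 (SE 0.59) and Fasn (-1.51, SE 0.37), Acaca (-1.29, SE 0.34), Srebf1 (-0.78, SE 0.20) and Slc2a4 (-0.96, SE 0.20) fell, and in males Mest rose by 3.24 (SE 0.69). In NZO/HlLtJ females Irs1 (-1, SE 0.17), Slc2a4 (-1.02, SE 0.20), Acaca (-1.29, SE 0.34), Insr (-0.32, SE 0.11) and Sfrp5 (-1.68, SE 0.54) fell and Ccl2 (2.44, SE 0.41), Adgre1 (1.21, SE 0.21) and Itgax (1.20, SE 0.32) rose. Without the doubted libraries C57BL/6J females gave 11 calls and males 267, and Mest and Sfrp5 in females had adjusted p = 0.182 and 0.268. Of the females on 10% fat this left replicates 2 and 4. Replicate 2 had Lep at 862 CPM, against 141 to 364 in the others of its group and 653 to 1616 on 44% fat. The fall to 11 calls therefore cannot be put down to the marked libraries alone. C57BL/6J females gave 385, 586 and 410 without 10% fat replicates 1, 3 and 4, 2474 without 10% fat replicate 2 and 485 without 44% fat replicate 3. C57BL/6J males gave 458, 146, 1529 and 104 without 44% fat replicates 1 to 4, and 429, 337 and 473 without 10% fat replicates 2 to 4. CAST/EiJ females gave 668 without 10% fat replicate 4. CAST/EiJ males gave 112 and 650 without 10% fat replicates 3 and 2, and 197 and 178 without 44% fat replicates 2 and 4. For CAST/EiJ as a strain, the count fell from 1709 to 1000 without male 10% fat replicate 1.

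**Figure D3:**
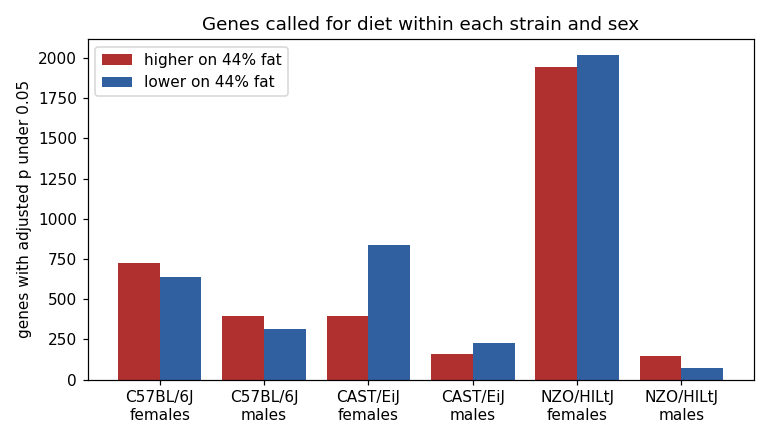
Number of genes with edgeR adjusted p below 0.05 for diet in each strain and sex, as bars for genes higher (red) and lower (blue) on 44% fat. NZO/HlLtJ females have 1942 higher and 2018 lower genes (66.7% higher under library totals), and NZO/HlLtJ males 147 and 71.

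**Figure D4:**
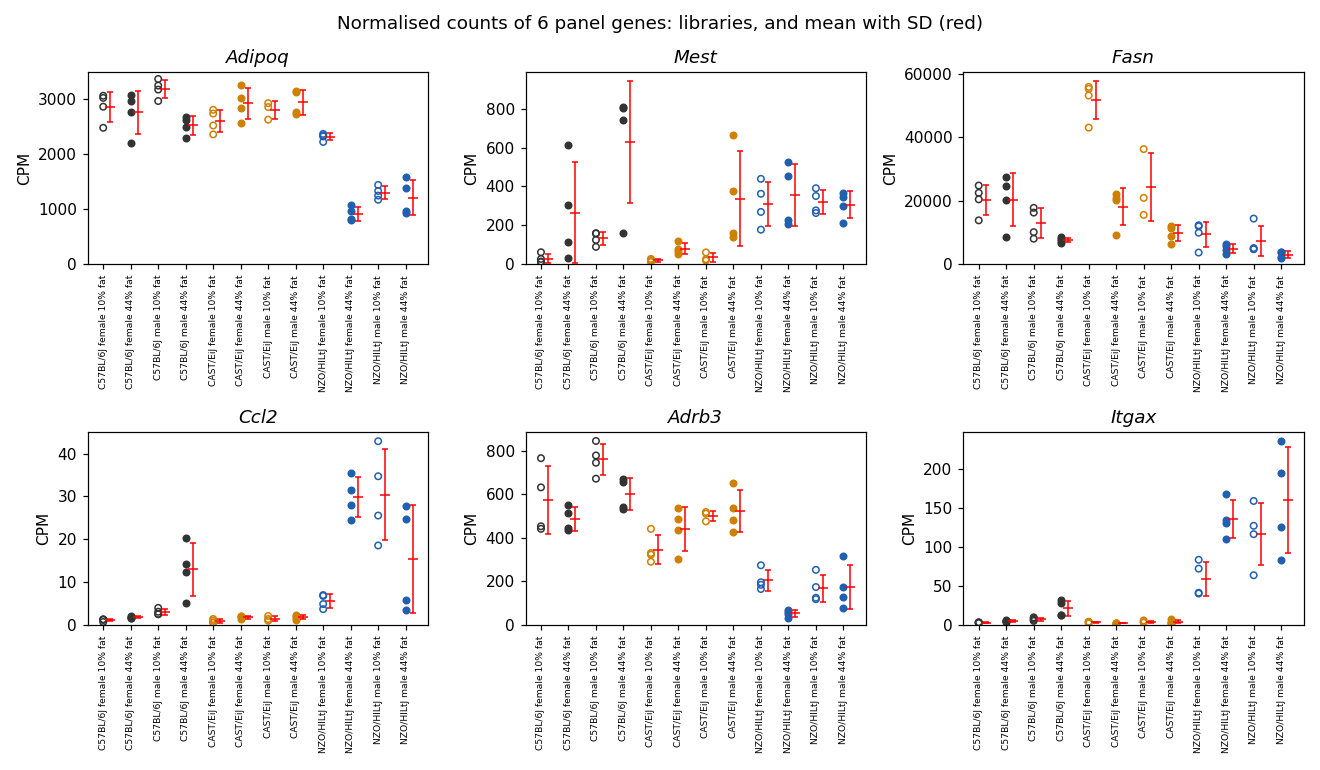
CPM of 6 genes in each library (circles, filled for 44% fat) by group, with the group mean and SD in red. Adipoq in NZO/HlLtJ females stands at 2318 ± 63.9 CPM on 10% fat and 915 ± 128 on 44%.

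On 10% fat the strains differed in most genes, and several were near absent in a strain. Fam213b stood at 26.7 ± 3.51 and 43.5 ± 5.47 CPM in C57BL/6J females and males and at 0.00527 and 0 in CAST/EiJ (n = 15), and Tmem45b at 81.7 ± 26.1 and 284 ± 95.3 against 0.113 and 0.0312. Rnase2a was higher in CAST/EiJ, at 84.2 ± 14.3 against 0.0401 ± 0.021 CPM in females (log2 9.38, SE 0.54, adjusted p = 4.25e-18). In total 11441 genes differed between CAST/EiJ and C57BL/6J, 10236 between NZO/HlLtJ and C57BL/6J and 12520 between NZO/HlLtJ and CAST/EiJ. The submitters name GRCm38, built from C57BL/6J, and the genome used for each strain is not given, so low values in CAST/EiJ or NZO/HlLtJ can stem from sequence differences, deletions or lower expression.

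Immune genes were among the strain differences of NZO/HlLtJ. Mndal, an interferon-inducible gene, stood at 30.9 ± 5.08 CPM in C57BL/6J females and 0.136 ± 0.0695 in NZO/HlLtJ (log2 -7.25, SE 0.19), and Zfp607 differed by -7.22 (SE 0.29). The inflammasome gene Nlrp1a was 0 in NZO/HlLtJ females and 0.569 ± 0.254 CPM in C57BL/6J females. Ctnna2, a neural catenin, was higher in NZO/HlLtJ (18.1 ± 1.39 against 0.0192 ± 0.0252 CPM in females), Tph2 stood at 36.2 ± 12 CPM in NZO/HlLtJ females and 0 in CAST/EiJ, and Serpina3j, at 0.0129 against 6.63 ± 1.85 CPM in females, was lower in NZO/HlLtJ than in CAST/EiJ. St6galnac5 and Wfdc17 were 0 in CAST/EiJ on 10% fat, against 7.03 ± 2.96 and 6.74 ± 1 CPM in C57BL/6J females, and Muc20 was 0 in C57BL/6J females against 6.41 ± 0.583 in CAST/EiJ. Nnt, which carries a deletion in C57BL/6J, was at 28.4 ± 1.22 CPM there and 56.6 ± 7.13 in CAST/EiJ females, but at 26.7 ± 1.59 in NZO/HlLtJ females, lower than in C57BL/6J over both sexes (-0.32, SE 0.05).

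Cell-type lists differed between strains on 10% fat. All 14 lipid-associated macrophage genes were higher in NZO/HlLtJ than in C57BL/6J, with adjusted p = 0.162 with an estimated correlation, and Itgax stood at 59.1 ± 22.0 CPM in NZO/HlLtJ females against 2.47 ± 0.296 in C57BL/6J. All 11 mesothelial genes were lower, with 0.325. In CAST/EiJ 14 of 16 interferon-stimulated genes were lower than in C57BL/6J (16 adjusted over the list alone), with a median of -2.82 and adjusted p = 0.196 with an estimated correlation. Lipogenesis genes were higher in CAST/EiJ, 16 of 20 (17 adjusted over the list alone), with Fasn at 51840 ± 5980 CPM in females against 20400 ± 4720 in C57BL/6J, and adjusted p = 0.643 with an estimated correlation. On 10% fat Cyp2e1 ranged over the 6 groups from 55.2 ± 43.5 CPM in NZO/HlLtJ males to 5574 ± 1940 in CAST/EiJ males.

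Several posterior HOX genes differed between the sexes on 10% fat. Hoxc10 was lower in males in each strain, by -7.21 (SE 0.27) in C57BL/6J, -8.03 (SE 0.33) in CAST/EiJ and -6.20 (SE 0.24) in NZO/HlLtJ, at 28.7 ± 2.69 against 0.189 ± 0.0621 CPM in C57BL/6J (adjusted p = 5.75e-23, n = 8). Hoxa10, at 17.3 ± 3.27 against 0.0736 ± 0.0373 CPM in NZO/HlLtJ, and Hoxa9 were lower in males of all 3 strains, as was Hoxa11, which was 0 in CAST/EiJ and NZO/HlLtJ males. Sex called 2472 genes in C57BL/6J, 2963 in CAST/EiJ and 1714 in NZO/HlLtJ. In NZO/HlLtJ sex on 10% fat also aligns with the ID range outside ORSAM77, with 67 genes called within ORSAM77 and 621 outside. Gonadal fat lies along the uterus and ovary in females and the epididymis in males, so sex and depot are not separable here.

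Some thermogenic genes and the estrogen-related Sult1e1 differed by sex, with the brown and beige fat list called in no strain with an estimated correlation. Ucp1, the uncoupling protein of brown fat, stood at 81.2 ± 64.9 CPM in C57BL/6J females and 0.0424 ± 0.0299 in males, and 10 of 13 brown and beige fat genes were lower in males, with adjusted p = 0.0598 with an estimated correlation. In CAST/EiJ Ucp1 was also lower in males (-3.73, SE 0.81), with 6 of 13 list genes, but in NZO/HlLtJ it was higher (2.47, SE 0.69), where 3 list genes were higher and 1 lower (median 0.97). With an estimated correlation the list was called in neither of the 2. Sult1e1, the estrogen sulfotransferase, was higher in males, at 0.0199 against 48.0 ± 16.8 CPM in C57BL/6J and 0.00647 against 3.22 ± 0.94 in NZO/HlLtJ. Nrn1 (-6.89, SE 0.27 in C57BL/6J), Ren1 (-6.07, SE 0.63 in CAST/EiJ), Cntn1 (-5.96, SE 0.56 in CAST/EiJ) and Asic2 (-4.95, SE 0.48 in NZO/HlLtJ) were lower in males. The Y-linked Uty reached 26.2 ± 1.75 CPM in C57BL/6J males. Without NZO/HlLtJ male 10% fat replicates 4 or 1 the NZO/HlLtJ count was 997 or 1089, and without CAST/EiJ male 10% fat replicate 3 the CAST/EiJ count was 1804.

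Some sex differences depended on single or doubted libraries. Ceacam10 stood at 726 ± 1450 CPM in C57BL/6J males and was 0 without C57BL/6J male 10% fat replicate 3. Muscle genes Myh4 (-6.76, SE 1.67) and Atp2a1 (-6.59, SE 1.34) were high in C57BL/6J females, and without the doubted libraries Myh4 was 1.45 and Atp2a1 -0.99, as the C57BL/6J count went from 2472 to 883. In CAST/EiJ males Rnase10 (184 ± 318 CPM) and Defb42 (24.7 ± 41.9), genes typical of the epididymis, had adjusted p = 0.817 and 0.0973 without CAST/EiJ male 10% fat replicate 3, and Cdh1, an epithelial cadherin, was at 18.9 ± 22.5 CPM. That library was not among the doubted ones, since no epididymis list could be scored.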

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

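The splits of the samples and the comparison within an ID range were written before their results were seen, and the other tests on patterns here were chosen after.

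Single samples stood far from the rest of their group by Dixon's ratio for 18 of 275 tests (24 panel genes and the library total in 11 groups of 4), where chance gives 13.75, about 1 in 20, and all 18 were panel genes. In C57BL/6J these were, in CPM, Pparg at 224 in female 10% fat replicate 3 (others 150 to 151), Sfrp5 at 3.86 in female 10% fat replicate 2 (1.68 to 1.83) and Col6a3 at 309 in male 10% fat replicate 1 (243 to 253). In C57BL/6J male 44% fat replicate 3 there were 4, Mest at 163 (others 741 to 808), Npr3 at 1042 (1931 to 2030), Acaca at 1391 (957 to 1020) and Irs1 at 85.9 (56.8 to 60.5). In CAST/EiJ they were Ucp1 at 62.1 in female 10% fat replicate 3 (534 to 570), Fasn at 9326 (20387 to 21985), Scd1 at 59422 (78483 to 81715) and Saa3 at 4.10 (2.22 to 2.43) in female 44% fat replicate 1, Col6a3 at 1198 in female 44% fat replicate 2 (469 to 518), Itgax at 6.64 in male 44% fat replicate 4 (2.36 to 2.90) and Tnf at 0.694 in male 44% fat replicate 2 (0.319 to 0.355). In NZO/HlLtJ male 10% fat replicate 2 was high in Fasn at 14392 (4741 to 5108) and Acaca at 1951 (591 to 764), Srebf1 was at 247 in female 10% fat replicate 3 (412 to 442) and Saa3 at 32.8 in male 44% fat replicate 3 (0.879 to 3.71).

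Diet effects averaged over the sexes differed between strains by a test of the difference, given in log2 units. NZO/HlLtJ minus C57BL/6J had Adipoq at -0.53, Mest at -2.67 and Sfrp5 at -3.36 among 1726 genes. CAST/EiJ minus C57BL/6J had Lep at -1.55, Sfrp5 at -1.83, Sqle at -1.31, Irs1 at 0.74 and Itgax at -1.55 among 1549. NZO/HlLtJ minus CAST/EiJ had Adipoq at -0.84, Mest at -2.56, Irs1 at -1.03, Adrb3 at -1.17 and Itgax at 1.14 among 1551. Between male and female effects 53 genes differed in CAST/EiJ and 2287 in NZO/HlLtJ, with Adipoq at 1.24, Sfrp5 at 2.47, Scd1 at 1.09, Irs1 at 0.84, Insr at 0.50, Adrb3 at 2.03, Adgre1 at -1.08 and Ccl2 at -3.42.

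Other splits of the same samples into groups of the same sizes were counted, the real split included. Regrouped samples carry the real effect in their spread, and splits for diet by strain or by sex regroup diet itself. A low share therefore does not by itself exclude chance. Counted below are the splits that called as many genes, held against a share of 0.05. For diet, 1 of 100 splits did so in C57BL/6J (3145, highest other 2894) and in CAST/EiJ (1709, highest other 1061), and 2 of 100 in NZO/HlLtJ (2364, highest other 3463). The larger NZO/HlLtJ split kept all 8 female libraries on their own diet and 4 of 8 males, so the female response is in it. Within a sex, 1 of 35 splits did so in C57BL/6J females (1368, highest other 1058) and males (711, 440), CAST/EiJ females (1232, 329) and males (388, 239) and NZO/HlLtJ females (3960, 6). In NZO/HlLtJ males 4 of 35 did (218, highest other 347), so chance is not excluded there, and of the 3 larger splits those with 347 and 329 genes kept 6 of 8 males on their own diet and that with 328 kept 4. None parted ORSAM81 from ORSAM88, though that with 329 had both ORSAM88 males on the same side.

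For diet by strain 1 of 100 splits did so for NZO/HlLtJ minus C57BL/6J (1726, highest other 576), CAST/EiJ minus C57BL/6J (1549, 300), NZO/HlLtJ minus CAST/EiJ (1551, 265) and any difference (3335, 333). For diet by sex 12 of 100 did in CAST/EiJ (53, highest other 830), so chance is not excluded. In C57BL/6J edgeR called 0 (1216 genes at unadjusted p below 0.05, DESeq2 58 and limma 12; highest other 2607), so all 100 splits call as many by construction and say nothing on chance. In NZO/HlLtJ 3 of 100 did (2287, highest other 2795). The 830 of CAST/EiJ is several times the real count, and its cause was not tested. The 830 kept all 8 females on their own diet and 3 of 7 males. The 2795 of NZO/HlLtJ exchanged all 8 females and 6 of 8 males, which is near the mirror of the real split. The other larger NZO/HlLtJ split, with 2345 genes, kept all 8 females on their own diet but only 4 of 8 males. The NZO/HlLtJ count alone therefore does not show a separate male response. For strain 1 of 100 did so in each pair (10236, highest other 3404; 11441, 8797; 12520, 8612) and for sex 1 of 35 in C57BL/6J (2472, 765), CAST/EiJ (2963, 1543) and NZO/HlLtJ (1714, 411). The number of gene lists called by camera was matched by 63 of 100 splits in C57BL/6J (9 lists, highest other 19), 18 in CAST/EiJ (11, 15) and 28 in NZO/HlLtJ (15, 20), so chance is not excluded for these counts of lists.

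The response of NZO/HlLtJ females and males to diet differed in 2287 genes. With the ID range as a term 1733 genes were called, 1598 of them among the 2287, which argues against handling that acted alike in all strains as the whole cause. The median ratio of male to female change over genes called in females was -0.00769 (-0.0997 to 0.115 without each male library). This argues against a male effect of the same size hidden by any single library. Male 44% fat replicates 1 and 4, at -60.4 and -66.4 on component 1, lay apart from replicates 2 and 3, both at -80.3. Leaving out 1 library at a time cannot tell whether such a pair masked a male effect. Handling specific to NZO/HlLtJ cannot be told apart from the sex difference, since the effects within ORSAM77 and outside it correlated across genes at 0.237, between the bounds of 0.1 and 0.3 set beforehand. Over the 75 genes called outside ORSAM77 the effect within it was 0.741 times as large by the median (0.469 to 1.15 without each library), but 4 of 36 assignments of the diets within the sexes gave a ratio as high (highest other 1.45). Whether males on 10% fat lie towards the female 44% fat profile stays open as well. The 2 differences, taken against separate females, correlated at 0.372 to 0.465 over 6 splits (0.135 to 0.310 in C57BL/6J, 0.135 to 0.197 in CAST/EiJ). Within ORSAM77 they correlated at 0.269 to 0.277, from fewer libraries per difference, which by itself can lower a correlation. Outside ORSAM77 both differences carry the same change of ID range. Sex itself stays open, as untested.

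Skeletal muscle genes fell on 44% fat in C57BL/6J females, with a median of -4.25. Without the 5 libraries marked by the same list the median was -0.356 over 8 of its 9 genes, and 14 genes in all were called in C57BL/6J females, where 5 fewer libraries were fitted. Muscle RNA in some of the 10% fat samples is a candidate source, with Myh4 at 42.5 ± 71.0 and Atp2a1 at 23.3 ± 37.3 CPM in that group and no gene of the list in another list. As the libraries were marked by the genes tested, a response of muscle genes in these animals stays open.

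Interferon-stimulated genes were lower in CAST/EiJ than in C57BL/6J on 10% fat, with a median of -2.82 against -0.0118 for all genes. Of 10000 random lists matched on expression 0 had a median as low (lowest -0.852), so the list lay below other genes of like expression. Scaling removes a loss of reads that is even over genes. Such a loss in a diverged strain could not have lowered a single list, so the draws do not test it. The list lay -1.13 (-1.25 to -0.802 without each library) below the lower of the macrophage and the T and NK cell medians, which argues against fewer leukocytes as the whole cause. Sequence divergence concentrated in these genes and a lower interferon tone of the strain stay open, and neither was tested.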

How the results depend on the processing

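No paired analysis was possible because the labels give no replicate numbers shared between groups. Leaving out doubted libraries and splitting NZO/HlLtJ by ID range were chosen after seeing the data. For the counts below that moved by over 1.5 times, the cause was not tested unless fewer samples give it.

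Named results include genes not called in the main fit, which count as kept when they stayed uncalled, in either direction. A weakened result lost its call and a strengthened one gained a call, so the numbers kept are not numbers of calls that held. With DESeq2 size factors 677 named results kept their calls or non-calls and 2 weakened. With library totals 651 kept them, 19 weakened and 9 strengthened; with the DESeq2 test 634, 2 and 10; with limma on the deposited values 627, 45 and 6; with the ID range as a term 660, 15 and 4; with only the strains compared 595, 46 and 8. Without a filter 669 kept them and 10 weakened, and under the stricter filter 658 kept them and 4 strengthened. Without doubted libraries 591 kept them, 82 weakened and 2 strengthened, and within ORSAM77 81 kept them and 93 weakened, and outside it 92 and 81, where fewer samples were fitted. Without single libraries 10878 kept them, 585 weakened and 50 strengthened. Reversed were Hoxa11 for diet in C57BL/6J (0.12) and Myh4 for sex in C57BL/6J (1.45) without doubted libraries, Xist for NZO/HlLtJ minus CAST/EiJ with limma (0.13), and Ceacam10 for sex in C57BL/6J, which was 0 without C57BL/6J male 10% fat replicate 3 and up to 18.27 without another library (a fitted value against females at 0 CPM, so no bound on a fold).

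Without doubted libraries, so with fewer samples, the counts were 1123 for diet in C57BL/6J, 11 in its females, 267 in its males, 698 in NZO/HlLtJ males, 841 for NZO/HlLtJ minus C57BL/6J, 715 for CAST/EiJ minus C57BL/6J, 1963 for any difference and 883 for sex in C57BL/6J. With only the strains compared they were 943 for diet in CAST/EiJ, 277 in C57BL/6J males, 623 in CAST/EiJ females, 23 in CAST/EiJ males, 1 in NZO/HlLtJ males and 1 for diet by sex in C57BL/6J and in CAST/EiJ. DESeq2 gave 1152 in C57BL/6J males, 641 in CAST/EiJ males, 605 in NZO/HlLtJ males, 58 for diet by sex in C57BL/6J and 158 in CAST/EiJ; its Wald test does not test any difference among 3 strains, which was not run. limma gave 247 in CAST/EiJ males and 12 for diet by sex in C57BL/6J. Library totals gave 2151 in CAST/EiJ females, 140 in NZO/HlLtJ males and 1 for diet by sex in C57BL/6J. NZO/HlLtJ males gave 144 without a filter and 99 with the ID range, and diet by sex in C57BL/6J gave 4 under the stricter filter.

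Within ORSAM77 edgeR called 19 genes for diet in NZO/HlLtJ, 10 in females, 0 in males (1768 at unadjusted p below 0.05), 0 for diet by sex (2320) and 67 for sex; outside it 68, 623, 0 (1274), 75 and 621. No other tool was run on these subsets. With an estimated correlation camera called 0 lists in each of the 3 strains, where the preset correlation gave 9, 11 and 15 and fry 5, 5 and 15. The correlation of diet effects between NZO/HlLtJ and C57BL/6J was 0.155 over genes called in either strain.

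The share of called genes that were higher moved by over 10 points under library totals, from 39.6% to 70.9% for diet in CAST/EiJ, 45.9% to 61.0% in NZO/HlLtJ, 32.3% to 75.9% in CAST/EiJ females and 49.0% to 66.7% in NZO/HlLtJ females. It moved from 39.2% to 51.3% for NZO/HlLtJ minus C57BL/6J, 38.7% to 65.4% for CAST/EiJ minus C57BL/6J, 52.3% to 39.5% for NZO/HlLtJ minus CAST/EiJ, 58.5% to 31.9% for diet by sex in CAST/EiJ, 51.5% to 32.7% in NZO/HlLtJ and 49.8% to 77.9% for sex in CAST/EiJ, and to 65.1%, 32.6% and 72.9% for the strains. limma gave 40.6% for diet by sex in NZO/HlLtJ and 83.8% in CAST/EiJ. The median of all genes moved under totals by 0.139 in CAST/EiJ females, -0.123 for diet by sex in CAST/EiJ, 0.129, -0.166 and 0.295 for the strains and 0.146 for sex in CAST/EiJ.

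Leaving out each library in turn, with fewer samples, gave from 2169 to 3886 genes for diet in C57BL/6J, 1000 (male 10% fat replicate 1) to 2100 in CAST/EiJ and 1542 (male 10% fat replicate 2) to 2667 in NZO/HlLtJ. Ranges were 385 (10% fat replicate 1) to 2474 (10% fat replicate 2) in C57BL/6J females, 104 (44% fat replicate 4) to 1529 (44% fat replicate 3) in C57BL/6J males, 668 (10% fat replicate 4) to 1356 in CAST/EiJ females, 112 (10% fat replicate 3) to 650 (10% fat replicate 2) in CAST/EiJ males, 3020 to 3576 in NZO/HlLtJ females and 15 (44% fat replicate 4) to 859 (44% fat replicate 3) in NZO/HlLtJ males. Diet by strain gave 1295 to 2309 (NZO/HlLtJ minus C57BL/6J), 899 (CAST/EiJ minus C57BL/6J, without CAST/EiJ male 10% fat replicate 1) to 2228, 1276 to 1966 (NZO/HlLtJ minus CAST/EiJ) and 2726 to 3959 (any difference). Diet by sex gave 0 to 41 in C57BL/6J (41 without female 10% fat replicate 2), 4 (male 10% fat replicate 3) to 362 (male 10% fat replicate 1) in CAST/EiJ and 1067 (male 44% fat replicate 1) to 3292 in NZO/HlLtJ. Strain gave 9703 to 10253, 10883 to 11294 and 12100 to 12351, and sex 1773 to 2758, 1804 (CAST/EiJ male 10% fat replicate 3) to 3354 and 997 (NZO/HlLtJ male 10% fat replicate 4) to 1820. Lists called numbered 8 to 14 in C57BL/6J (14 without female 10% fat replicate 1), 7 to 11 in CAST/EiJ (7 without female 44% fat replicate 4) and 14 to 19 in NZO/HlLtJ. The correlation of diet effects ranged from 0.0547 to 0.108, 0.0563 to 0.135 and -0.0175 to 0.0303. On simulated data 59.7% of genes changed 1.5-fold were called in C57BL/6J, so smaller changes can be missed at this depth and group size.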

Other observations

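No further hypothesis was tested in this part; the imprinted genes were brought together, and the NZO/HlLtJ medians by ID range taken, after the values were seen. Zim1 rose in CAST/EiJ (1.84, SE 0.39) and NZO/HlLtJ (1.44, SE 0.37) and stood at 0.05 (SE 0.37) in C57BL/6J. The test of the difference from C57BL/6J called it in CAST/EiJ (1.79, SE 0.53) and not in NZO/HlLtJ (1.39, SE 0.52). In NZO/HlLtJ it differed by sex (2.84, SE 0.73), at 2.92 ± 1.62 against 21.3 ± 17.6 CPM in males. Nnat differed from C57BL/6J (1.66, SE 0.49) and NZO/HlLtJ (1.93, SE 0.49) in CAST/EiJ, and was at 17.0 ± 14.8 CPM in CAST/EiJ females on 10% fat against 150 ± 71.9 in C57BL/6J and 297 ± 86.0 in NZO/HlLtJ females. For Peg3 no difference between strains was called, with 0.93 (SE 0.48) for CAST/EiJ minus C57BL/6J. Dlk1 fell in CAST/EiJ (-1.03, SE 0.31) and NZO/HlLtJ (-0.88, SE 0.29). Its CAST/EiJ call ended in 5 of 15 fits without a library, at -0.95 without female 10% fat replicate 1, -0.95 and -0.90 without female 44% fat replicates 1 and 4, -0.74 without male 10% fat replicate 1 and -0.86 without male 44% fat replicate 3.

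List results for diet outside the report were as follows, as genes risen and fallen, with those adjusted over the list alone in parentheses. In C57BL/6J they were 2 and 3 for adipocyte identity (2 and 5), 2 and 5 for lipogenesis (2 and 6), 1 and 2 for fatty acid oxidation (1 and 2), 0 and 3 for brown and beige fat (0 and 3), 2 and 1 for macrophage (2 and 1), 3 and 2 for progenitor (3 and 2), 3 and 0 for cell cycle (7 and 0), 2 and 1 for insulin signalling (2 and 1), 2 and 3 for antioxidant (3 and 5), 0 and 2 for unfolded protein response (0 and 2), 0 and 2 for mammary (0 and 2), 1 and 0 for glucocorticoid (1 and 0), 2 and 0 for T and NK cell (0 and 0), 2 and 0 for circadian clock (0 and 0), 0 and 2 for oxidative phosphorylation (0 and 0) and 0 and 1 for mesothelial genes (0 and 0). Among B and plasma cell genes Ighm rose and Ms4a1 fell.

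In CAST/EiJ they were 3 and 1 for adipocyte identity (3 and 2), 2 and 0 for expansion (3 and 0), 2 and 0 for fatty acid oxidation (4 and 0), 1 and 1 for brown and beige fat (1 and 1), 3 and 0 for matrix (3 and 0), 0 and 3 for mitochondrially encoded (0 and 4), 0 and 1 for lipid-associated macrophage (0 and 1), 0 and 2 for T and NK cell (0 and 2), 3 and 1 for progenitor (4 and 3), 1 and 1 for interferon-stimulated (1 and 1), 3 and 3 for insulin signalling (5 and 3), 0 and 4 for antioxidant (0 and 4), 0 and 1 for immediate early (0 and 1) and 0 and 1 for mammary genes (0 and 1). Of the ovary, oviduct and uterus list 1 rose and 1 fell when adjusted over the list alone (median 0.21). The unfolded protein response list was called higher by camera (median 0.16), but not with an estimated correlation.

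In NZO/HlLtJ they were 1 and 1 for fatty acid oxidation (1 and 0), 1 and 2 for brown and beige fat (1 and 3), 3 and 0 for inflammatory (3 and 0), 2 and 0 for T and NK cell (2 and 0), 6 and 0 for endothelial (7 and 0), 4 and 0 for matrix (6 and 0), 2 and 3 for progenitor (2 and 3), 3 and 0 for interferon-stimulated (3 and 0), 0 and 3 for mitochondrially encoded (0 and 7), 0 and 1 for cholesterol synthesis (0 and 1), 0 and 3 for insulin signalling (0 and 3), 1 and 5 for antioxidant (1 and 6), 1 and 1 for unfolded protein response (1 and 1), 0 and 1 for circadian clock (0 and 1) and 1 and 0 for immediate early genes (1 and 0). camera called the erythrocyte list lower (median -0.52), which neither fry nor camera with an estimated correlation did. The median, the mean and the direction given by camera differed in sign for progenitor, insulin signalling, antioxidant, glucocorticoid and erythrocyte genes in C57BL/6J, for inflammatory, insulin signalling, circadian clock, mammary and erythrocyte genes in CAST/EiJ, and for expansion, ovary and muscle genes in NZO/HlLtJ, and camera called none of these.

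In NZO/HlLtJ females the list medians within ORSAM77 and outside it were -0.76 and -0.50 for adipocyte identity, 1.09 and 1.00 for macrophage, 1.64 and 1.22 for cell cycle, -1.44 and -1.25 for mesothelial, 1.51 and 1.14 for inflammatory and 1.16 and 0.26 for interferon-stimulated genes. T and NK cell genes stood at 1.22 and -0.05, with a mean log2 CPM of 2.54 in female 44% fat replicate 1 against 0.916 in replicate 2. In NZO/HlLtJ males B and plasma cell genes stood at -1.15 and 2.78, the latter with a mean log2 CPM of 4.36 in the doubted male 44% fat replicate 3 against 1.17 in replicate 4.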
